A study of Homo sapiens with 8 samples.

How the data were processed

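RNA from 2 human choriocarcinoma cell lines, JEG3 and BeWo, was measured on HG-U133 A oligonucleotide arrays, with 3 arrays labelled JEG3 and 5 labelled BeWo. The labels name the arrays by letter and do not say whether letters mark separate cultures, so p-values measure the spread between these arrays, which may be technical. The labels give all 8 arrays the same lot. The number of arrays limits the precision.

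The deposited value table holds log2 values for 22283 probe sets, from 3.52 to 14.22, with array medians from 6.75 to 6.84. How the authors summarised and scaled the deposited log2 values is not given in the sources used here, and their centring stays unknown. The log2 scale itself was read from the values, since the table's control probe sets rose with a slope of 0.776 against the log2 of the signals in the array reports over 59 controls. Each array also has a deposited expression report with linear signals of control probe sets scaled to a target of 2500 by the statistical algorithm (alpha1 0.05, alpha2 0.065, tau 0.015), per the file headers. The table holds no detection call per probe set, so a low value cannot be separated from background.

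The columns labelled BeWo B and BeWo C hold the same value as JEG3 B and JEG3 C in all 22283 probe sets. The 8 reports differ from each other, so control probe sets of each shared column were set against the reports of both labels. The distance was the root mean square difference of 14 housekeeping controls, as log2 differences from JEG3 A. By that distance the columns labelled BeWo B and BeWo C lay nearer the JEG3 reports, and they were left out. This departs from the design fixed before the data were examined, which fitted all 8 columns. The choice was made after the columns were seen and before the result of any fit was seen, and the fit on all 8 columns is given beside it. Among the 5 distinct columns other than the reference JEG3 A, 4 lay nearest their own report, and BeWo D lay nearer the JEG3 C report. In 3 further versions with z scores, over 14, 27 and 59 controls, 3, 4 and 4 of these 5 columns lay nearest their own report. The report of BeWo B or BeWo C was never the nearer of its pair in any version.

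AFFX controls (68 probe sets) were left out. A probe set was kept when it lay above its array's 50th percentile on at least 3 of the 6 columns, which left 11561 probe sets. The deposited scaling was kept, as the array medians lay within 0.082 of each other. Probe sets carry 1 gene symbol in 19071 cases, several in 1043 and none in 2169 in the platform annotation, and no symbol changed when matched to the gene table of assembly GRCh38.p14. No gene was named from a probe set with several symbols. For this reason CGB3 and CGB5, which share a probe set with other symbols, have no value of their own here. ERVW-1 and ERVFRD-1 have no probe set of their own in this annotation either. Each of 7208 genes was represented by 1 probe set, with those ending in _x_at used only where a gene had no other and the highest mean value deciding. Probe sets ending in _s_at or _x_at can match transcripts of more than 1 gene.

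Lines were compared with limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. Differences are JEG3 minus BeWo, in log2 units. Counts of genes at least 2-fold apart need a log2 difference of at least 1. Of 20 gene lists fixed before the data were examined, 19 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Named genes were chosen by a rule fixed before the data were examined. It takes the 12 largest differences per direction among genes past the threshold whose arrays do not overlap, up to 3 members per list that pass at 2-fold or more, and 11 symbols named in any case. XIST and Y-linked genes were not named.

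The array reports of all 8 arrays were compared by two-sided exact permutation tests over 56 splits, whose smallest p is 0.0179. The design named the 3' to 5' ratios and the spike levels. The other report measures among the 13 tested were added after the files were seen. Run sets were read from the reports as a technical batch: JEG3 A, B and C share run set 1, BeWo A and B run set 2, BeWo C run set 3, and BeWo D and E run set 4. No run set holds both lines, so the planned batch block could not be fitted, and the run set entered as a random block (duplicateCorrelation) instead. That fit needs cameraPR for the lists. A first version gave cameraPR moderated t values and called 7 lists. It was changed, after that result was seen, to z scores, the scale camera itself uses, because moderated t values already called 6 lists with no block. Both counts are given with the alternatives.

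The fit was tested on simulated data made from the means and spread of the 6 columns, with 200 probe sets changed in each of 10 runs of the comparison of JEG3 with BeWo and a median of 11290.5 probe sets kept. It recovered 36.3% of 1.5-fold, 73.0% of 2-fold and 93.3% of 4-fold changes, and 5.0% of its calls were false. The real fit called a far larger share, 5191 of 11561 probe sets. Its columns also share run sets, while the simulated columns vary independently, so these rates need not hold for it. With a shift of 0.5 in 1 list, camera called the shifted list in 20 of 20 runs and 2 of 309 unshifted lists, on a median of 7050.5 genes. The simulated genes are uncorrelated, so this does not test the lists against correlated genes. Alternatives covered scaling, filters, variance model, array weights, probe set choice, set test and leaving out each array. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.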

Results

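Gene expression was compared between JEG3 and BeWo, a pair of cell lines grown from human choriocarcinoma, a malignant tumour of trophoblast, the epithelium of the placenta. Arrays labelled JEG3 numbered 3 and arrays labelled BeWo numbered 5. Per-array median values were 6.83, 6.84 and 6.82 for JEG3 A, B and C, and 6.79, 6.81 and 6.75 for BeWo A, D and E. The columns labelled BeWo B and BeWo C were equal to JEG3 B and JEG3 C in every probe set. For the HUMRGE 5' control, a ribosomal RNA probe set, the column labelled BeWo C held 10.48, while the control's signal was 23009.2 in the JEG3 C report and 389.6 in the BeWo C report. The comparison therefore rests on 3 JEG3 columns (A, B, C) and 3 BeWo columns (A, D, E), a choice made after the columns were seen. Columns of the same line correlated across probe sets at r = 0.985 to 0.996 and columns of different lines at r = 0.947 to 0.954. Probe sets are not independent replicates.

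The question the labels pose is how expression differs between the lines. BeWo held far more MMP2, LGALS3 and HMOX1 transcript, and JEG3 far more ANXA3, FABP5 and FN1. MMP2, a matrix-degrading protease, read 6.26 ± 0.12 in JEG3 and 12.35 ± 0.04 in BeWo (log2, SD, n = 3), 68.1-fold higher in BeWo (limma adjusted p = 1.13e-08). FN1, which encodes the matrix protein fibronectin, read 12.28 ± 0.13 in JEG3 and 7.01 ± 0.07 in BeWo (log2, SD, n = 3), 38.8-fold higher in JEG3 (limma adjusted p = 1.13e-08). Of 7208 genes, 3263 (45.3%) passed the threshold, 1414 higher in JEG3 and 1849 higher in BeWo. At least 2-fold differences were called for 376 genes higher in JEG3 and 553 higher in BeWo. At least 4-fold differences were called for 72 and 95. With single arrays left out, the counts ran from 241 genes at 2-fold higher in JEG3 and 621 in BeWo without JEG3 A to 401 and 415 without BeWo D. The filter still asked for 3 columns, so genes above the median only in the line with an array left out could not pass. The change in balance is therefore set in part by the filter. Among the 929 genes called at 2-fold, 824 had a value without JEG3 A and 823 kept their direction. Without BeWo D 816 had a value and 815 kept it. With the run set of the arrays as a random block, 2926 genes were called, 375 at 2-fold or more higher in JEG3 and 554 in BeWo. No run set holds both lines, so this block cannot separate run set from line. The arrays of the lines did not overlap for 55.8% of genes, where chance gives 10%. On all 8 columns as labelled, limma called 0 genes (100 at an unadjusted p under 0.05, lowest adjusted p = 0.453). Without any of the 4 columns that share values, which leaves JEG3 A alone against BeWo A, D and E, it called 951 genes, 244 of them at least 2-fold higher in JEG3 and 406 in BeWo. Of the 929 genes called at 2-fold, 803 had a value there and 667 were at least 2-fold apart in the same direction. JEG3 A and BeWo A, D and E are also in the main fit, so this is no independent check. Genes above the median only in JEG3 could not pass the filter of 3 columns there, which lowers the count for JEG3.

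Among the 12 largest differences higher in JEG3 were ANXA3, a calcium-dependent phospholipid-binding protein (55.5-fold), FABP5, a fatty acid-binding protein (42.7-fold), COL3A1, a fibrillar collagen chain (28.3-fold), and TMSB4X, an actin-binding peptide (27.1-fold). MARCKS (15.9-fold), MBNL2 (15.8-fold), CAPN6 (log2 difference 3.81), SLC7A11 (13.7-fold), LRP2 (13.3-fold), ADGRL2 (13.0-fold) and DPP4 (12.6-fold) completed them with FN1. The MARCKS difference depends on the probe set used, with 5.20-fold over the median of its probe sets, 9.53-fold by its probe set with the lowest p and 2.36-fold without _x_at and _s_at probe sets. With BeWo A as the only BeWo array MARCKS was 31.0-fold higher in JEG3. The standard errors of these log2 differences ran from 0.11 for DPP4 to 0.35 for MARCKS. FABP5 and TMSB4X have near-identical copies elsewhere in the genome and were read by _s_at probe sets, so their values are uncertain in that respect. Higher in BeWo were LGALS3, a galactose-binding lectin (58.3-fold), TMT1A (37.4-fold), HSPA2, a heat shock protein (34.7-fold), NT5DC2 (32.9-fold), HMOX1, which degrades haem (22.7-fold), and PLTP, which transfers phospholipids between lipoproteins (21.8-fold). PHLDA2 (17.5-fold), the chemokine receptor CCR7 (17.5-fold), LMO2 (17.3-fold), GDF15 (15.2-fold) and MUC4 (14.6-fold) followed, all 12 including MMP2 with limma adjusted p of at most 4.25e-06. GDF15 was read by an _x_at probe set, and its other probe set, which did not pass the filter, differed by 0.0014. For 20 of these 24 genes the lower line lay below the array median on all of its arrays, where a value cannot be told from background, so these folds compare measured values and are not exact transcript ratios. Probe sets with several gene symbols are given without a gene name. Of 588 tested, 142 were higher in JEG3, the largest difference being 38.9-fold (limma adjusted p = 1.13e-08), and 154 in BeWo, the largest being 64.4-fold (limma adjusted p = 2.46e-07).

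**Figure D1:**
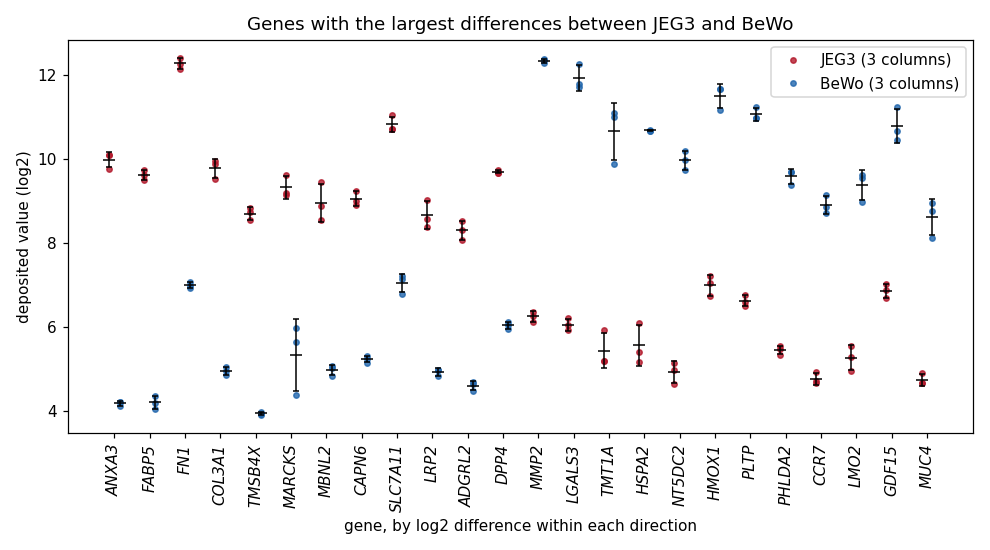
Deposited log2 value (vertical axis) of the 24 genes with the largest differences (horizontal axis), with each column as a point and bars for mean and SD over 3 columns per line. For FN1 the JEG3 columns centre on 12.28 and the BeWo columns on 7.01, and for MMP2 they centre on 6.26 and 12.35.

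Of 16 tested protein hormone genes of the placenta, 2 were higher in JEG3, 6 were higher in BeWo and 8 did not pass, with the same counts adjusted over the list alone. CGA, the alpha subunit shared by chorionic gonadotropin and pituitary hormones, read 10.42 ± 0.27 in JEG3 and 13.38 ± 0.18 in BeWo (log2, SD, n = 3), 7.77-fold higher in BeWo. No CGB gene has a probe set of its own here. Probe sets that CGB genes share were tested and are counted above among those with several symbols, without a gene name. The 64.4-fold difference given there was read by such a probe set, at 5.63 ± 0.26 in JEG3 and 11.64 ± 0.49 in BeWo (log2, SD, n = 3). Another was 4.15-fold higher in BeWo. These values cannot be assigned to any single CGB gene. ADM, which encodes adrenomedullin, was 4.15-fold higher in BeWo. The list as a whole did not pass (camera adjusted p = 0.259). Of 14 steroid synthesis genes, 2 were higher in JEG3, 4 in BeWo and 8 did not pass, again with the same counts adjusted over the list alone (camera adjusted p = 0.493). CYP11A1, which starts steroid synthesis from cholesterol, was 7.01-fold higher in BeWo, and CYP19A1, the aromatase that makes oestrogens, was 4.32-fold higher in BeWo. HSD3B1, which makes progesterone from pregnenolone, was 5.32-fold higher in JEG3.

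Of 21 trophoblast fusion genes, 8 were higher in JEG3, 5 in BeWo and 8 did not pass, and adjustment over the list alone gave the same counts (camera adjusted p = 0.327). HOPX (7.62-fold) and SDC1 (4.30-fold) were higher in BeWo and the amino acid transporter gene SLC1A4 (3.52-fold) in JEG3. GCM1, a transcription factor of syncytiotrophoblast, was 2.18-fold higher in BeWo (limma adjusted p = 0.001), not called without the 4 shared columns, where JEG3 A stands alone, though the difference was -1.13 there and -1.12 here (limma adjusted p = 0.0644). Of 27 genes of invasive extravillous trophoblast, 9 were higher in JEG3, 9 in BeWo and 9 did not pass, as when adjusted over the list alone (camera adjusted p = 0.966). MMP2 led those higher in BeWo, and FN1 and DPP4 those higher in JEG3. This list's median of 0.11 and mean of -0.18 differed in sign. HLA-G, a class I molecule of extravillous trophoblast, was 1.49-fold higher in JEG3 (limma adjusted p = 0.00347), with all 4 of its probe sets in that direction, and was not called without the shared columns at a difference of 0.56 against 0.58 here (limma adjusted p = 0.111). HLA-C was 1.26-fold higher in JEG3 (limma adjusted p = 0.0264), but only 3 of its 4 probe sets went that way. The HLA-C difference was 0.34 here and 0.10 over the median of its probe sets (limma adjusted p = 0.5). It was not called either under median scaling (0.29, limma adjusted p = 0.0521), at differences of 0.26 to 0.37 without JEG3 A (limma adjusted p = 0.0811), JEG3 B (0.112), BeWo D (0.0725), BeWo E (0.0586) or the shared columns (0.211), or at 0.19 with BeWo A as the only BeWo array (0.262). Sequences of HLA genes are alike and all their probe sets here end in _x_at. ASCL2 did not pass the filter, with values of 4.04 ± 0.17 in JEG3 and 4.83 ± 0.60 in BeWo (log2, SD, n = 3).

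Of 32 genes of trophoblast stem cells and cytotrophoblast, 13 were higher in JEG3, 10 in BeWo and 9 did not pass, also when adjusted over the list alone (camera adjusted p = 0.395). PEG10 (4.44-fold), the growth factor receptor genes FGFR2 (4.34-fold) and EGFR (10.18 against 8.18 in BeWo, log2 means) were higher in JEG3. EGFR was 1.86-fold higher over the median of its probe sets and 2.35-fold with BeWo A as the only BeWo array, and PEG10 6.84-fold by its probe set with the lowest p. Without the 4 shared columns EGFR was not called, at a difference of 2.06 with JEG3 A alone (limma adjusted p = 0.0548). Of 21 imprinted genes, 7 were higher in JEG3, 4 in BeWo and 10 did not pass, as adjusted over the list alone (camera adjusted p = 0.259). PHLDA2 was higher in BeWo, and ZNF331 (5.59-fold) and PEG10 in JEG3. Of 40 placental transporter genes, 17 were higher in JEG3, 12 in BeWo and 11 did not pass, as adjusted over the list alone (camera adjusted p = 0.259). FABP5, the cystine transporter gene SLC7A11 and the endocytic receptor gene LRP2 led them. ABCG2, a drug efflux pump, read 10.40 ± 0.13 in JEG3 and 11.40 ± 0.51 in BeWo (log2, SD, n = 3, limma adjusted p = 0.00518), not called without the shared columns at a difference of -0.92 with JEG3 A alone (limma adjusted p = 0.156). ABCB1 did not pass the filter, with 4.51 ± 0.06 in JEG3 and 4.51 ± 0.15 in BeWo (log2, SD, n = 3).

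Genes of epithelial junctions and keratins were the list that passed: of 26 tested, 15 were higher in JEG3, 4 in BeWo and 7 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.00361). The call did not hold with an estimated correlation (adjusted p = 0.636 with an estimated correlation). The desmosomal plakophilin gene PKP2 (6.83-fold) and the keratin gene KRT19 (2.41-fold) were higher in JEG3, and KRT23 (5.69-fold) in BeWo. With no filter PKP2 was 2.71-fold higher in JEG3, read by another probe set that did not pass the filter. Of 17 mesenchymal genes, 4 were higher in JEG3, 5 in BeWo and 8 did not pass, and 5 and 5 were called when adjusted over the list alone (camera adjusted p = 0.869). FN1, COL3A1 and COL5A2 (8.99-fold) were higher in JEG3. The median of this list was -0.01 and its mean 0.19. Of 20 basement membrane and matrix genes, 5 were higher in JEG3, 3 in BeWo and 12 did not pass, as adjusted over the list alone (camera adjusted p = 0.695). NID1 (5.85-fold), SDC1 and GPC4 (3.05-fold) were higher in BeWo. NID1 was 3.34-fold higher over the median of its probe sets. Another probe set stood for it under the filter that asks for values above the median on every array, at 1.91-fold. The same held without BeWo D (1.75-fold), without BeWo E (1.95-fold) and without both (1.68-fold). The NID1 probe set of the main fit read 9.21, 9.83 and 9.69 on BeWo A, D and E, against a JEG3 mean of 7.03 (log2). These smaller folds thus come from the change of probe set. The median of the matrix list was 0.14 and its mean -0.07.

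Of 19 interferon response genes, 10 were higher in JEG3, 3 in BeWo and 6 did not pass, as adjusted over the list alone (camera adjusted p = 0.0604). IFIT1 (3.52-fold) was higher in JEG3, and the peptide transporter gene TAP1 (2.88-fold) and BST2 (2.78-fold) in BeWo. BST2 was not called without the 4 shared columns, at a difference of -1.38 with JEG3 A alone against -1.47 here (limma adjusted p = 0.0631). Of 22 antigen presentation genes, 7 were higher in JEG3, 8 in BeWo and 7 did not pass, as adjusted over the list alone (camera adjusted p = 0.869). PDIA3 (4.01-fold), the immunoproteasome subunit gene PSMB8 (3.34-fold) and CALR (2.95-fold) were higher in BeWo. Under stricter filters CALR was read by another probe set and differed by -0.41 (limma adjusted p = 0.133 and 0.15). Over the median of its probe sets CALR was 1.67-fold higher in BeWo. With BeWo A as the only BeWo array CALR was 1.55-fold higher, again by another probe set. The CALR probe set of the main fit read 8.21 on BeWo A, against a JEG3 mean of 6.56 (log2). The antigen presentation list had a median of 0.08 and a mean of -0.26.

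Of 42 genes of DNA replication and mitosis, 3 were higher in JEG3, 19 in BeWo and 20 did not pass, as adjusted over the list alone (camera adjusted p = 0.0604). The cyclin genes CCNE1 (6.83-fold) and CCNB1 (3.89-fold) and TYMS (2.30-fold), which makes thymidylate, were higher in BeWo. Of 33 hypoxia and glycolysis genes, 6 were higher in JEG3, 14 in BeWo and 13 did not pass, with 6 and 15 adjusted over the list alone (camera adjusted p = 0.12). BHLHE40 (7.39-fold), ADM and the lactate dehydrogenase gene LDHA (2.73-fold) were higher in BeWo. BHLHE40 was 4.15-fold higher over the median of its probe sets and 4.66-fold with BeWo A as the only BeWo array. Of 18 p53 target genes, 3 were higher in JEG3, 10 in BeWo and 5 did not pass, as adjusted over the list alone (camera adjusted p = 0.0604). GDF15, TIGAR (3.72-fold) and the apoptosis gene BAX (3.22-fold) were higher in BeWo. Of 18 cholesterol synthesis genes, 7 were higher in JEG3, 2 in BeWo and 9 did not pass, with 8 and 2 adjusted over the list alone (camera adjusted p = 0.326). INSIG1 (3.13-fold) and NSDHL (2.64-fold) were higher in BeWo.

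Of 18 WNT pathway genes, 5 were higher in JEG3, 5 in BeWo and 8 did not pass, with 5 and 7 adjusted over the list alone (camera adjusted p = 0.938). The receptor gene FZD7 (6.04-fold) was higher in JEG3, and GSK3B (2.23-fold) and SFRP1 (2.32-fold) in BeWo. SFRP1 differed by -1.22 here and by -1.08 without the shared columns, where it was not called (limma adjusted p = 0.214). With BeWo A as the only BeWo array it differed by -0.40 (limma adjusted p = 0.0951). Of 7 cancer-testis genes, 4 were higher in JEG3, 2 in BeWo and 1 did not pass, as adjusted over the list alone (camera adjusted p = 0.259). PRAME (8.78-fold) was higher in BeWo, and MAGEB2 (8.03-fold) and MAGEA1 (2.26-fold) in JEG3. Markers of other cell types were few above the filter. Of 9 leukocyte markers, 2 were higher in each line and 5 did not pass, as adjusted over the list alone (camera adjusted p = 0.762), and LCP1 was 2.27-fold higher in BeWo. Only 4 endothelial markers were tested, too few for the list test, with 2 higher in BeWo, 3 adjusted over the list alone, and ENG 2.84-fold higher in BeWo.

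**Figure D2:**
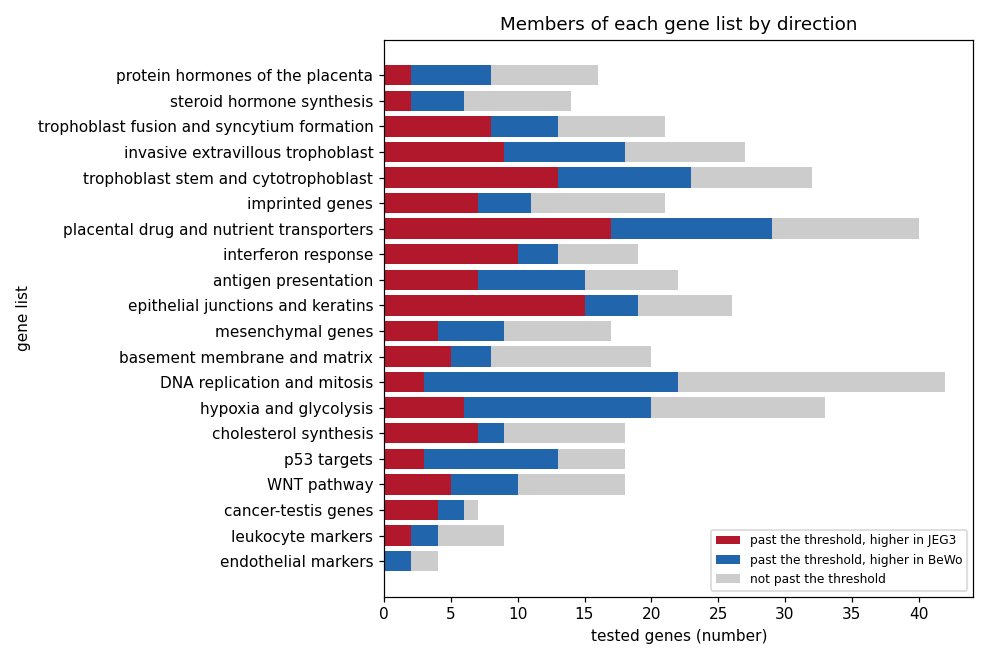
Number of tested genes (horizontal axis) in each of 20 gene lists (vertical axis), split by whether a gene passed the threshold higher in JEG3, higher in BeWo or not at all. Epithelial junctions and keratins show 15 genes higher in JEG3 and 4 in BeWo, and DNA replication and mitosis 3 and 19.

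The array reports are separate for all 8 arrays and do not depend on the shared columns. The ISGF3A control, a probe set group for a factor of the interferon response, had a mean signal of 3603 ± 92.4 (SD, n = 3) in JEG3 and 1664 ± 589 (SD, n = 5) in BeWo. Taken as geometric means the signal was 2.25-fold higher in JEG3, with every JEG3 array above every BeWo array (two-sided exact permutation p = 0.0179, the smallest 56 splits allow, and 0.058 after adjustment over 13 report measures). The gap was smaller in the value table, where the 3' probe set of the ISGF3A control read 9.72, 9.64 and 9.50 in JEG3 A, B and C and 8.95, 9.36 and 9.38 in BeWo A, D and E (log2). Its 5' probe set read 6.42, 6.29 and 6.29 against 5.51, 6.08 and 5.28 there (log2). The scale factor averaged 9.45 ± 1.51 in JEG3 and 18.4 ± 2.79 in BeWo (SD), with the same exact p of 0.0179 and adjusted 0.058. Noise averaged 5.80 ± 0.40 and 2.81 ± 0.53 (SD) with the same pair of values. No run set holds arrays of both lines, so differences between the lines in any report measure cannot be told apart from differences between run sets. Background averaged 88.6 ± 7.17 in JEG3 and 60.6 ± 15.6 in BeWo (SD, exact permutation p = 0.0714). The GAPDH 3' to 5' signal ratio, a measure of RNA integrity, was 0.910 ± 0.029 and 0.892 ± 0.072 (SD, exact permutation p = 0.696), and that of beta-actin 1.08 ± 0.11 and 1.28 ± 0.16 (SD, exact permutation p = 0.107). Hybridisation spike signals averaged 13975 ± 1561 and 11300 ± 1799 (SD, exact permutation p = 0.0893). Probe sets called present made up 49.5% ± 2.61 in JEG3 and 48.5% ± 1.42 in BeWo (SD, exact permutation p = 0.5). Of the other 5 measures, the signal of the ISGF3A 3' probe set alone had the smallest exact p (0.0179), and the signals of beta-actin (0.0536), M27830 (0.304), GAPDH (0.821) and HUMRGE (0.839) had higher ones. The HUMRGE control signal was 9381 on BeWo D and 9956 on BeWo E, against 438 to 784 on BeWo A, B and C, and was 878 on JEG3 A, 2185 on JEG3 B and 6650 on JEG3 C. In the value table the 3' control of 28S ribosomal RNA was 12.40 on BeWo D and 11.84 on BeWo E, against 7.68 to 8.62 on BeWo A and JEG3 A, B and C (log2). The middle control was 8.68 and 9.34 against 6.28 to 6.65, and the 5' control 6.97 and 8.05 against 5.12 to 5.63 (log2). BeWo D and BeWo E thus stand apart in these controls of 28S ribosomal RNA. The M27830 controls did not all set them apart. The 3' one read 8.04 and 7.83 on BeWo D and BeWo E, against 7.93 on JEG3 C (log2). The 5' one read 8.74 and 10.42 against 8.70 on JEG3 C, and the middle one 10.64 and 11.49 against 9.87 on BeWo A (log2). The 5' control of 18S ribosomal RNA was high on JEG3 C as well (11.40, against 11.47 and 10.73 on BeWo D and BeWo E, log2). Without BeWo D and BeWo E, which leaves BeWo A alone, 785 of the 929 genes called at 2-fold had a value. Of these, 612 were at least 2-fold apart in the same direction. Genes above the median only in BeWo could not pass the filter of 3 columns there. That fit therefore cannot show what these arrays contribute to the balance of directions.

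**Figure D3:**
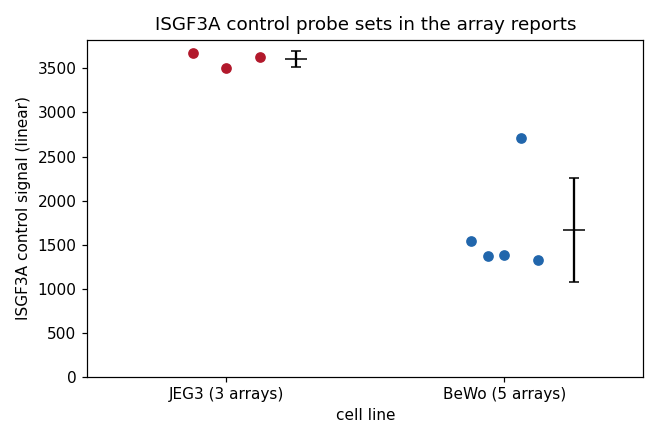
Linear signal of the ISGF3A control (vertical axis, mean over its 5', middle and 3' probe sets on the log scale) on each of 8 arrays by cell line (horizontal axis), with mean and SD beside the points. JEG3 averages 3603 and BeWo 1664, with BeWo D at 2706.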

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

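The tests of the equal columns, of run sets and of other splits of the columns were chosen after the results were seen, and the test of background was not. Among 13 report measures over the 5 BeWo arrays, where chance sets apart about 1 group in 20, 1 stood apart. The ISGF3A control signal of BeWo D was 2706, against 1321 to 1544 on the other BeWo arrays, a gap of 0.839 of the range where 0.71 is the limit. With BeWo D left out, the log2 difference of JEG3 from BeWo was 1.36 in place of 1.17 (exact permutation p = 0.0286).

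The columns labelled BeWo B and BeWo C equal those of JEG3 B and JEG3 C. Separate arrays that happen to agree are argued against, since no pair of distinct columns shared more than 9 values. Under JEG3 values entered under the BeWo B and BeWo C labels, the shared columns should lie nearer the JEG3 reports, and they did in 8 of 8 comparisons (2 pairs in 4 versions of the match). BeWo values entered under the JEG3 B and JEG3 C labels had 0 of these 8. In the first version the distances were 0.379 to the JEG3 B and 1.27 to the BeWo B report, and 0.462 to the JEG3 C and 1.60 to the BeWo C report. The match is coarse, as in 4 of the 8 comparisons the nearest of all reports was that of JEG3 A, so a mix-up among JEG3 arrays stays open. It can also miss the line, as BeWo D lay at 0.392 from the JEG3 C report and 0.478 from its own. The shared columns correlated with the JEG3 A column at r = 0.9955 and 0.9922. With BeWo A, D and E they correlated at r = 0.9469 to 0.9537, which also argues against BeWo values.

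Among the 7208 genes kept by the filter, more differed 2-fold between the lines than between run sets of BeWo. The lowest count between a JEG3 and a BeWo column was 940. That was 8.62 times the highest count between BeWo columns of different run sets, 109. Genes above the median only on BeWo A, or only on BeWo D and BeWo E, could not pass the filter of 3 columns. Genes above it in a whole line could, which favours the count between lines. The BeWo counts also compare only BeWo A with BeWo D or BeWo E, and the JEG3 run set does not enter them. The ratio therefore cannot decide whether run differences account for the difference between the lines. Measured background averaged 88.6 in JEG3 and 60.6 over all 5 BeWo arrays (exact permutation p = 0.0714). On BeWo A, D and E, the BeWo arrays of the fit, it was 71.7, 41.7 and 46.1. An additive offset as the source of most 2-fold calls is nevertheless argued against, since 32.7% of them lay in the brightest of 3 equal parts of the genes. The real split called 3263 genes and the highest of the other splits 0, but 10 splits are too few for a share under 0.05. Every other split mixes both lines in each group, so a large difference between lines or run sets widens its spread. The 0 calls therefore say nothing of the source of the difference. All JEG3 arrays lie in a single run set, so an offset of that run set alone, and the untested biological difference between the lines, both stay open.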

How the results depend on the processing

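The fits on all 8 columns, without the 4 shared columns, without BeWo D and BeWo E and with the run set as a random block were chosen after seeing the data. Main counts were 5191 probe sets, 3263 genes, 376 genes at 2-fold higher in JEG3, 553 higher in BeWo, and 1 list. With all 8 columns as labelled, limma called 0 probe sets, 0 genes and 0 in either direction at 2-fold, as its construction puts the same values in both lines. Without the 4 shared columns the counts were 1430 probe sets, 951 genes and 244 higher in JEG3, with 1 array in an arm assumed to vary like the others. Without BeWo D and BeWo E, 360 genes were higher in BeWo and 7 lists passed, again with a lone array in an arm and the spread taken from JEG3. A filter at the 75th percentile left 3287 probe sets and 246 genes higher in JEG3, and one above the median on every array 228, as fewer probe sets were tested. Without _x_at and _s_at probe sets 2274 probe sets, 1915 genes, 214 and 325 were called, also among fewer tested. Testing against a minimum difference gave 132 and 140. With no filter 4 lists passed, with an estimated correlation 0 (fry, which asks another question, 13), and the cause was not tested. With each array left out in turn, 2-fold genes higher in JEG3 ranged from 241 (without JEG3 A) to 401 (without BeWo D). Those higher in BeWo ranged from 415 (without BeWo D) to 621 (without JEG3 A). Lists ranged from 1 to 7 (5 without BeWo A, 7 without BeWo D, 6 without BeWo E). The filter kept its minimum number of columns, so genes above the median only in the line with an array left out could not pass. The ranges of gene counts are therefore set in part by the filter and do not show the weight of single arrays alone. The same limit applies to the counts without the 4 shared columns and without BeWo D and BeWo E. The random run-set block gave 2926 genes and 1 list with z scores, or 7 with moderated t, against 1 and 6 with no block, so most of that change came with the form of the statistic. As no run set holds both lines, the block cannot separate run set from line. With no filter GDF15 showed no difference (0.0014, limma adjusted p = 0.994), as a dimmer probe set that the filter leaves out stood for it. The ISGF3A difference kept its direction with each array left out. Its exact permutation p was 0.0571 without BeWo A, B, C or E, at log2 differences of 1.10 to 1.16 against 1.17 on all arrays. Fewer splits are possible with an array left out, so this p moves in coarser steps there. No paired analysis was possible because only the letter A is shared by the usable columns of both lines. The pseudocount alternatives were not run, as the values are log2, and the planned batch block could not be fitted. Without detection calls, low values cannot be told from background.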

Other observations

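Gene families described here, and the test of them, were chosen after the main results were seen, while the tests of neighbouring genes were set before their results. Of 17 tested histone genes, 10 were higher in JEG3, 2 in BeWo and 5 did not pass, with a median log2 difference of 0.85 (camera adjusted p = 0.0054 over 16 families, adjusted p = 0.336 with an estimated correlation). H2AC6 (7.04-fold), H2BC5 (4.06-fold) and H2BC12L (3.93-fold) led them in JEG3, though probe sets of histone genes can read near-identical copies. Of 8 annexin genes, 5 were higher in JEG3 and 0 in BeWo (camera adjusted p = 0.00555, adjusted p = 0.336 with an estimated correlation), with ANXA1 7.15-fold and ANXA9 2.14-fold higher after ANXA3. Of 6 S100 genes, 5 were higher in JEG3 and 0 in BeWo, among them S100A14 (3.60-fold), S100P (2.62-fold) and S100A13 (2.12-fold), with the same adjusted p values as the annexins.

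Of 48 mitochondrial ribosomal protein genes, 0 were higher in JEG3, 23 were higher in BeWo and 25 did not pass (camera adjusted p = 0.00555, adjusted p = 0.748 with an estimated correlation). MRPS28 (2.64-fold), MRPL42 (2.42-fold) and MRPL13 (2.32-fold) led these. Cytosolic ribosomal protein genes went both ways, with 13 higher in JEG3, 10 in BeWo and 30 not past the threshold (camera adjusted p = 0.497). Of 38 heat shock genes, 3 were higher in JEG3 and 17 in BeWo (camera adjusted p = 0.0588), with DNAJC15 12.2-fold and HSPB8 4.90-fold higher in BeWo beside HSPA2. Of 32 proteasome subunit genes, 5 were higher in JEG3 and 16 in BeWo (camera adjusted p = 0.0611). The other 9 families had adjusted p from 0.0787 to 0.992.

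A hypothesis of DNA copy number differences between the lines was tested by whether neighbouring genes shift together. Windows of 25 neighbouring tested genes with a median shift beyond 0.648 log2, the 95th percentile of the largest shift in 1000 shuffles of gene order, lay in 7 separate regions, all higher in BeWo. Medians over whole regions ran from -0.59 to -0.76, and the largest window in each from -0.71 to -0.95. Their end genes, seen after the values, were UBXN2B to E2F5, IRF4 to TDP2, ME2 to ADNP2, PRRC2C to ASPM, ATR to KPNA4, CNIH4 to CHRM3, and GLT8D1 to MITF, and 68.8% to 92.3% of a region's genes went the same way. Gene family members lying side by side are argued against, since 7 regions stayed when neighbours with the same symbol stem were reduced to 1 gene. In simulations over 7201 genes, shifts of 0.5, 1 and 1.5 in 30 neighbours raised the number of regions in 1, 9 and 10 of 10 runs. Whether the added region overlapped the shifted neighbours was not checked. With no shift, 1 run showed a region. Smaller or further regions may thus be missed, and shared regulation of neighbours stays open.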
